A study of Homo sapiens with 6 samples.

How the data were processed

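RNA of 6 HaCaT cultures was hybridised to Affymetrix arrays of 54675 probe sets, 3 cultures at ambient pressure and 3 under a negative pressure gradient of 125 mmHg, each for 12 h. Groups and replicate numbers were taken from the sample titles, which name 3 biological replicates per condition. The authors deposited log2 values that had been background-corrected, normalized between arrays and summarised per probe set by RMA in Affymetrix Expression Console 1.2, per the submitters' processing notes. The scale was checked against the values, which lay between 0.890 and 13.4 with array medians of 3.81 to 3.89. Array batches, scan dates and any filter are not given in the sources used here, and scanner files were not used here.

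The platform annotation gave 41091 probe sets 1 gene symbol, 1801 several and 11721 none here, with 62 Affymetrix controls counted apart. The gene identifiers of 41037 probe sets matched the RefSeq gene table, and 0 symbols needed an update. No gene was named from a probe set with several symbols. Each of 19775 genes was represented by the probe set with the highest mean over the 6 arrays among those naming it alone. No filter on low values was applied.

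Negative pressure was compared with ambient pressure with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with default prior, no trend and no block, and Benjamini-Hochberg adjustment over all genes, at an adjusted p under 0.05. A fold change is negative minus ambient pressure on the log2 scale, and every adjusted p of a gene comes from this limma fit unless another is named. Before the data were examined, 37 gene lists were fixed with 682 different genes, of which 611 were measured. The lists were tested two-sided with camera of limma at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists, each with at least 5 measured genes. Of these lists, 1 entered the test and its adjustment but is not reported here. Counts adjusted over the list alone use Benjamini-Hochberg within the list. Camera with an estimated correlation was an alternative, and so was fry, which tests whether the genes of a list move on balance in 1 direction, or in either direction, and does not compare them with other genes.

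The rule for naming genes was fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose mean lay above the median gene mean. It also took up to 4 members with the smallest p in the direction of each list past camera, up to 3 changed members of each other list, and always CDH1, CTNND1, CTNNB1, CTNNA1, CDH3 and SRC. Genes named beyond this rule are said to have been singled out after their values were seen.

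The groups share replicate numbers 1 to 3. Across genes, the deviations from the group means correlated at 0.27 between the replicates numbered 1, 0.27 between those numbered 2 and 0.53 between those numbered 3, each above 0.1, so the numbers were taken to pair the cultures. The pairing rests on this check and not on a stated shared day or batch. Ambient replicate 1 correlated more with negative pressure replicate 2 (0.43), and ambient replicate 2 correlated at 0.15 with negative pressure replicate 1. Deviations cancel out within a group. An offset shared by the replicate 3 arrays alone would therefore also raise the values among replicates 1 and 2. The check does not show that the cultures numbered 1, or those numbered 2, were paired. The fit without the block stayed the main one, as fixed beforehand, and blocked values stand beside it where they change a call.

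Alternatives fixed beforehand were the replicate block, quantile normalization repeated, median centring, cyclic loess, leaving out the genes of lowest mean (13183 of 19775 kept), the mean of all probe sets of a gene or the probe set with the largest variance, trend and robust variance, array weights, every probe set tested, other thresholds, and leaving out each array in turn. Leaving out both replicate 3 arrays, and replicate 3 as a batch term, were added after seeing the data. The fit and the list test were tested on simulated data: 10 simulations of 19775 genes with 200 changed genes and the measured spreads, 3 arrays per group. In these, 37.8% of 1.5-fold and 96.2% of 2-fold changes were recovered in the right direction, with 6.82% false among the calls. A list shifted by 0.3 on the log2 scale was called in 10 of 10 simulations and the other lists in 0. Noise was drawn independently for each gene, with no correlation between genes and no offset of replicate 3. These runs therefore do not show how often the list test calls unshifted lists of correlated genes.

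The 3' to 5' control probe sets were compared with an exact permutation test, whose smallest p is 0.1 for 3 arrays against 3. For arrays, the number of replicates limits the precision. Probe sets with no gene or several were tested apart with the same limma fit, with their own adjustment. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.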

Results

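Gene expression was measured in HaCaT cells, a spontaneously immortalised line of human epidermal keratinocytes, on 6 Affymetrix arrays of 54675 probe sets. RNA of 3 cultures kept for 12 h under a negative pressure gradient of 125 mmHg was set against RNA of 3 cultures kept at ambient pressure. The values are on the log2 scale, each gene is represented by 1 probe set, and 19775 genes were compared. The number of arrays, 3 per group, limits the precision of every value. Across probe sets, which are not independent replicates, Pearson's r was 0.997 between replicates 1 and 2 at ambient pressure and 0.996 between replicates 1 and 2 under negative pressure. Pairs within a group that included replicate 3 gave 0.990 and 0.992 at ambient pressure, and 0.989 and 0.990 under negative pressure.

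The first principal component carried 42.2% of the variance and set the replicate 3 arrays of both groups (20.3 and 31.1) apart from the other 4 arrays, which lay between -18.3 and -9.07. Pressure separated on the second component, with 30.9% of the variance: the ambient arrays lay between 10.9 and 23.6 and the negative pressure arrays between -15.6 and -15.2. As a sign of RNA quality, the 3' minus 5' difference of the ACTB control probe sets was 0.54 ± 0.25 on the log2 scale at ambient pressure and 0.69 ± 0.24 under negative pressure (SD, n = 3 each; exact two-sided permutation test, p = 0.5). For GAPDH it was 0.18 ± 0.03 and 0.10 ± 0.06 (exact two-sided permutation test, p = 0.2). The smallest p that 3 arrays against 3 allow in this test is 0.1.

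**Figure D1:**
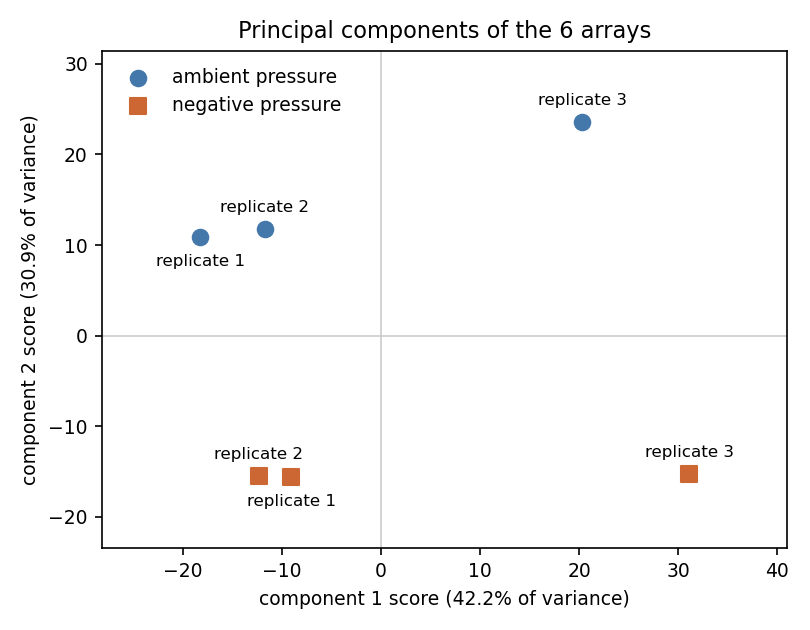
Scores of the 6 arrays on the first principal component (horizontal axis, 42.2% of the variance over 19775 genes) and the second (vertical axis, 30.9%), with circles for ambient and squares for negative pressure. The replicate 3 arrays of both groups lie at 20.3 and 31.1 on the first component, to the right of the other 4, and the groups separate on the second.

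The comparison asked which transcripts of keratinocytes differed after 12 h of negative pressure. AQP3, the water and glycerol channel of the basal keratinocyte membrane, showed the largest rise among the genes named here, 3.82-fold. HSPB1, a small heat shock protein, rose 2.32-fold, and DDIT4, an inhibitor of mTORC1 signalling, 2.36-fold. The largest fall among the genes named here was that of the long non-coding RNA DLEU2, 3.12-fold, followed by PDK1, a kinase that inhibits pyruvate dehydrogenase, 2.80-fold, and CIRBP, a cold-inducible RNA-binding protein, 2.52-fold. In all, 182 of 19775 genes passed an adjusted p of 0.05 in limma, 120 of them higher (65.9%) and 62 lower under negative pressure. Folds ran from 1.51 to 3.82 with a median of 1.80, and 53 genes changed at least 2-fold, 38 up and 15 down. For each of the 182 genes the 3 negative pressure arrays lay wholly above or below the 3 ambient arrays, which held for 17.3% of all genes against 10% by chance.

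With the replicate number as a block, 976 genes passed (568 higher, 408 lower), including all 182. The share of higher genes was 56.3% with cyclic loess (135 higher, 105 lower) and 54.9% with the probe set of largest variance (95 higher, 78 lower). Leaving out 1 array gave 12 genes without ambient pressure replicate 1, 7 without ambient replicate 2, 102 without ambient replicate 3, 18 without negative pressure replicate 1 and 7 without negative pressure replicate 2. Leaving out both replicate 3 arrays, an alternative chosen after seeing the data, gave 372.

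AQP3 went from 7.16 ± 0.19 at ambient to 9.09 ± 0.17 under negative pressure (SD, n = 3 each), a log2 fold change of 1.93 ± 0.14 (SE; limma adjusted p = 0.00248). CLU, the secreted chaperone clusterin, went from 8.06 ± 0.05 to 9.33 ± 0.07 (log2 fold change 1.27, adjusted p = 0.00466), and HSPB1 from 10.20 ± 0.08 to 11.41 ± 0.11 (adjusted p = 0.00538). TMT1A, a thiol methyltransferase, rose by 1.79 (adjusted p = 0.00466) and RSRP1 by 1.70 (adjusted p = 0.0220). ELF3, an epithelium-specific ETS transcription factor, rose by 1.45 (adjusted p = 0.0172), and MIR205HG, the host transcript of the epithelial microRNA miR-205, by 1.40 (adjusted p = 0.0259). The remaining large rises were those of GIMAP2 (1.36), LOC105379499 (1.35), the histone gene H2AC6 (1.25), DDIT4 (1.24) and PIGL (1.23), an enzyme of glycosylphosphatidylinositol anchor synthesis, with adjusted p from 0.00484 for LOC105379499 to 0.0220 for GIMAP2.

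DLEU2 went from 6.53 ± 0.20 to 4.89 ± 0.17, a log2 fold change of -1.64 ± 0.14 (adjusted p = 0.00466), PDK1 from 6.60 ± 0.47 to 5.11 ± 0.29 (-1.49, adjusted p = 0.0278) and CIRBP from 8.26 ± 0.09 to 6.92 ± 0.34 (-1.33, adjusted p = 0.0157). INHBA, the subunit of activin A, fell from 9.01 ± 0.31 to 7.88 ± 0.22 (adjusted p = 0.0273), and FOSL1, an AP-1 subunit, from 9.81 ± 0.23 to 8.77 ± 0.36 (adjusted p = 0.0467). Falls were also measured for the long non-coding RNAs WAKMAR2 (-1.23) and LINC01806 (-1.21), for TMEM68 (-1.18), DMAC2L (-1.16), the xanthine dehydrogenase gene XDH (-1.12), TMEM201 (-1.07) and the RNA helicase gene DDX51 (-1.03), with adjusted p from 0.00751 for LINC01806 to 0.0273 for TMEM68.

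Of the 41 genes that the naming rule took and that passed, all kept their direction when any 1 array was left out, and 5 (AQP3, CLU, DLEU2, LOC105379499 and TMT1A) also stayed past the threshold each time. As the groups of these genes did not overlap, leaving out 1 array could not turn a direction. The kept direction is therefore no test of them. Probe sets of 1 gene did not always move together: of 110 changed genes with more than 1 probe set, 65 (59.1%) had all others with the same sign. The mean of all probe sets of a gene ended the calls of DLEU2 (-0.38), CIRBP (-0.37), PIGL (-0.02, turned in sign), TMEM68 (-0.61), INHBA (-0.66), TMEM201 (-0.61) and DDX51 (-0.48). It left AQP3 (1.03, below RSRP1 and others), TMT1A (0.47), RSRP1 (1.11), PDK1 (-0.74), DMAC2L (-0.62) and XDH (-0.70) past the threshold at a smaller change. Such means can take in dim probe sets: those of DLEU2 beside the main one had means of 1.54 to 3.74, against 5.71. TMEM68 and TMEM201 each had another probe set of similar brightness (6.10 and 6.39), which stood at -0.04 and -0.14. The probe set with the largest variance ended the calls of CLU (1.12, adjusted p = 0.155) and of FOSL1 (adjusted p = 0.0601), the latter at an unchanged -1.04 on its 1 probe set.

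**Figure D2:**
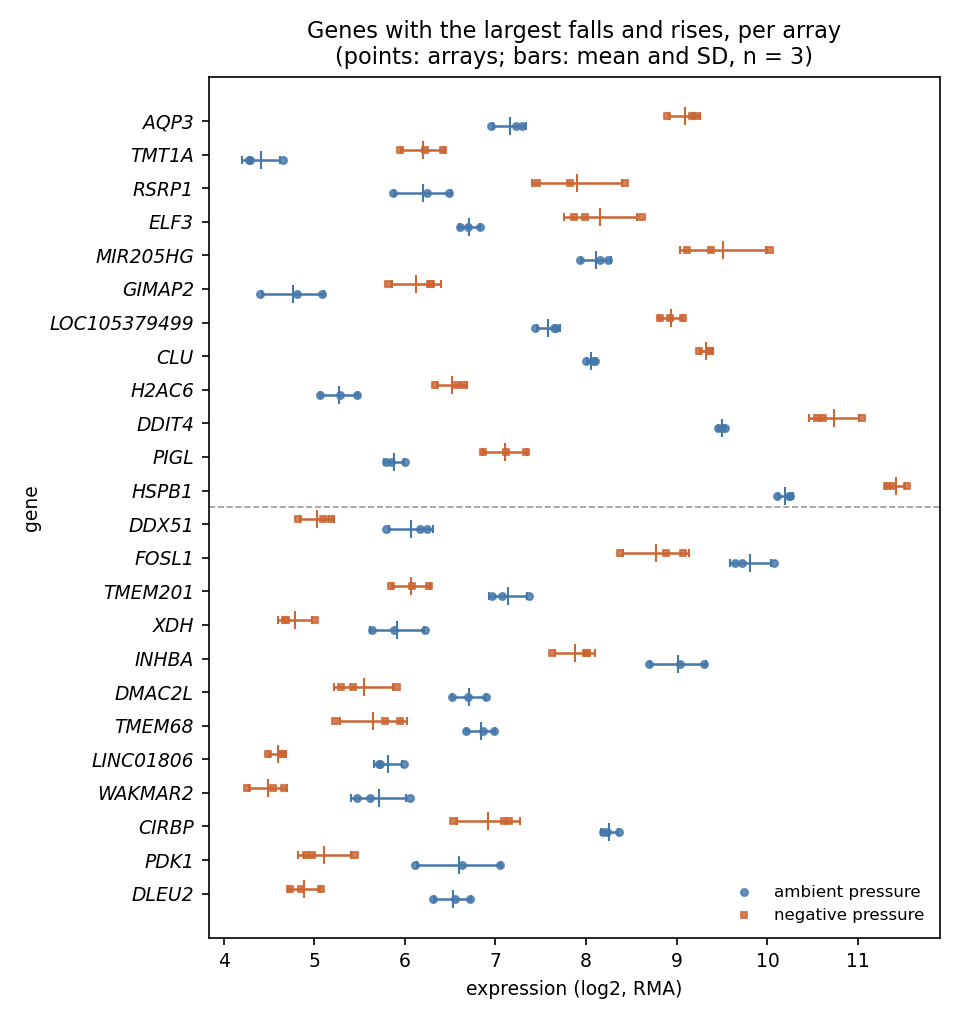
Expression per array (horizontal axis, log2 RMA values) of the 12 genes with the largest falls (below the dashed line) and the 12 with the largest rises (above it) among those named by the rule, with points for the 3 arrays of each group and bars for mean and SD. The groups do not overlap for any of these genes, and AQP3 lies at 7.16 ± 0.19 at ambient and 9.09 ± 0.17 under negative pressure.

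Gene lists fixed before the data were examined were compared with all other genes. Genes of the ATF4 and unfolded protein response were higher under negative pressure as a group, with a median log2 fold change of 0.32 over 24 measured members (camera adjusted p = 1.07e-05; adjusted p = 0.238 with an estimated correlation). Of these, 4 rose, none fell and 20 did not pass, and adjusted over the list alone 7 rose and 1 fell. With the replicate block 8 rose and 1 fell over all genes. The 4 were PHGDH, the first enzyme of serine synthesis (0.93 ± 0.11, SE; adjusted p = 0.0127), asparagine synthetase ASNS (1.17 ± 0.17, adjusted p = 0.0220), the transcription factor CEBPB (0.74 ± 0.11, adjusted p = 0.0247) and the glutathione-degrading enzyme CHAC1 (0.75 ± 0.12, adjusted p = 0.0265). The 1 that fell over the list alone was EDEM1 (-0.54), singled out after its value was seen, with an adjusted p over all genes of 0.197, and of 0.0173 with the replicate block. With the mean of all its probe sets ASNS stood at 0.48 (adjusted p = 0.15). That mean takes in a dim probe set (mean 1.89 on the log2 scale, against 8.42 for the main one), which stood at -0.21. The list joins ATF4 targets with unfolded protein response genes, which were not tested apart. Of the latter, HSPA5 stood at -0.10 (adjusted p = 0.885) and DNAJB9 at 0.14 (0.755), both singled out after their values were seen. Of the 24 members, 19 lay above 0.

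The heat shock list had a median of 0.25 over 13 measured members, all above 0 (adjusted p = 2.00e-05; adjusted p = 0.238 with an estimated correlation). The median was 0.46 without negative pressure replicate 3 and 0.16 without negative pressure replicate 2. HSPB1 rose and 12 members did not pass, and adjusted over the list alone 4 rose: HSPB1, FKBP4, HSPE1 and HSPH1. FKBP4, a co-chaperone of HSP90, stood at 0.52 ± 0.10 (SE; adjusted p = 0.0643, with the replicate block 0.0195), the mitochondrial chaperonin gene HSPE1 at 0.46 ± 0.12 (0.151, block 0.0360) and HSPH1 at 0.54 ± 0.18 (0.252, block 0.0178). Of the NRF2 targets, AKR1B10, an aldo-keto reductase, rose by 0.82 ± 0.12 (adjusted p = 0.0247) and 18 of 19 did not pass, with a list median of 0.22 (adjusted p = 0.000716; adjusted p = 0.238 with an estimated correlation). Adjusted over the list alone 2 rose, AKR1B10 and AKR1C3 (0.54 ± 0.11, adjusted p = 0.0742, block 0.0188). TXNRD1 (0.47, block 0.0310) and FTL (0.33) did not pass over all genes.

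Of 17 autophagy and lysosome genes, 3 rose and 14 did not pass, and the same 3 passed adjusted over the list alone. These were the autophagy kinase gene ULK1 (1.04 ± 0.14, SE; adjusted p = 0.0182), GABARAPL1 (0.81 ± 0.12, adjusted p = 0.0259) and the cargo receptor gene SQSTM1 (0.64 ± 0.11, adjusted p = 0.0325). MAP1LC3B stood at 0.27 (adjusted p = 0.502). The list had a median of 0.18 (adjusted p = 0.0262; adjusted p = 0.566 with an estimated correlation). Its call was lost without ambient pressure replicate 3 (adjusted p = 0.276) and without negative pressure replicates 1 (0.115) or 2 (0.0631), without both replicate 3 arrays (0.0552), with genes of low mean left out (0.0719) and in fry (0.186). Its median was 0.04 without negative pressure replicate 1 and 0.37 with the probe set of largest variance. SQSTM1 stood at 0.35 (adjusted p = 0.116) with the mean of all its probe sets. Of its probe sets beside the main one, the brightest (mean 6.94) stood at 1.02 and the rest between -0.08 and 0.11.

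Notch pathway genes were higher as a group, all 13 above 0 with a median of 0.20 (adjusted p = 0.000239; adjusted p = 0.238 with an estimated correlation). None of the 13 passed over all genes, where 5 had an unadjusted p under 0.05 in limma, and adjusted over the list alone 4 rose. Over all genes, 3 rose with the replicate block, and the median was 0.35 with the probe set of largest variance. The 4 were the target gene HES1 (0.57 ± 0.13, SE; adjusted p = 0.0906, block 0.0183), the receptor gene NOTCH1 (0.59 ± 0.13, 0.0930, block 0.0114), HEY1 (0.40) and the ligand gene JAG2 (0.40). In the TGF-beta list, SMAD6, an inhibitory SMAD of BMP signalling, rose by 0.91 ± 0.14 (adjusted p = 0.0251), and 16 of 17 did not pass. Adjusted over the list alone 6 rose, and with the replicate block 5 rose and 1 fell over all genes. The 1 that fell was the ligand gene TGFB2 (-0.44, adjusted p = 0.349, block 0.0399). The list joins TGF-beta genes with genes of BMP signalling, such as SMAD6, which were not tested apart. Its shift therefore does not show a response to TGF-beta itself. ID1 stood at 0.75 ± 0.18 (adjusted p = 0.116, block 0.00343), ID3 at 0.49 ± 0.12 (0.117, block 0.0236) and SMAD3 at 0.40 ± 0.12 (0.194). The TGF-beta list median was 0.20 (adjusted p = 0.0122; adjusted p = 0.238 with an estimated correlation). It was 0.32 without ambient pressure replicate 1, 0.31 without negative pressure replicate 3 and 0.13 without negative pressure replicate 1. The TGF-beta call was lost without ambient pressure replicate 3 (0.0522), without negative pressure replicate 1 (0.0704), with the mean of all probe sets (median 0.13, adjusted p = 0.101) and with the probe set of largest variance (median 0.10, adjusted p = 0.126). SMAD6 stood at 0.19 (adjusted p = 0.565) with the mean of its probe sets.

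Among interferon-stimulated genes the transcription factor gene IRF1 rose by 1.02 ± 0.17 (SE; adjusted p = 0.0318) and 22 of 23 did not pass. Adjusted over the list alone 3 rose: IRF1, XAF1 (0.47 ± 0.11, adjusted p over all genes 0.112, block 0.0337) and IRF9 (0.45 ± 0.12, 0.140, block 0.0350). OAS1 stood at 0.44 (adjusted p = 0.254). With the replicate block 5 members rose and 1 fell over all genes. The list median was 0.17 (adjusted p = 0.00446; adjusted p = 0.238 with an estimated correlation). Fatty acid and lipid genes had a median of 0.09 (adjusted p = 0.0286; adjusted p = 0.238 with an estimated correlation). None of its 15 members passed over all genes, where 4 had an unadjusted p under 0.05 in limma. PDK4, like PDK1 a pyruvate dehydrogenase kinase, was the 1 that rose over the list alone (1.13 ± 0.22, adjusted p over all genes 0.0557, block 0.00507). ELOVL4 (0.50, block 0.0332), ABCA12 (0.41) and SCD (0.36, from 0.24 to 0.44 when 1 array was left out) did not pass. PDK4, ELOVL4 and ABCA12 were dim, with means of 3.35, 3.26 and 2.62 on the log2 scale, below the median gene mean. Their changes therefore rest on weak signals, whereas SCD was bright (mean 9.98). The other probe sets of PDK4, dimmer still at means of 1.76 and 2.49, stood at -0.08 and 0.06. The lipid median was 0.14 without ambient pressure replicate 1, 0.18 without ambient replicate 2 and 0.15 without negative pressure replicate 3. It was 0.06 with cyclic loess, 0.22 with the probe set of largest variance, 0.15 with array weights and 0.16 without both replicate 3 arrays. The lipid call was lost without ambient pressure replicate 3 (0.0990) or negative pressure replicate 1 (0.0839), with array weights (0.0684), with the probe set of largest variance (0.0588) and with genes of low mean left out (0.504).

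Ribosome biogenesis genes were lower as a group, 16 of 18 below 0 with a median of -0.21 (adjusted p = 4.34e-05; adjusted p = 0.292 with an estimated correlation). No member passed over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05 in limma, and with the replicate block 3 fell. The median was -0.12 with array weights and -0.10 without both replicate 3 arrays. WDR43 stood at -0.85 ± 0.26 (SE; adjusted p = 0.213, block 0.00212), NOP14 at -0.44 ± 0.13 (0.210), RRS1 at -0.42 ± 0.14 (0.264) and WDR12 at -0.37 ± 0.10 (0.168). DNA replication and S phase genes had a median of -0.16 over 23 members (adjusted p = 0.000505; adjusted p = 0.569 with an estimated correlation), with no member past either threshold and 5 at an unadjusted p under 0.05 in limma. CDC45, part of the replicative helicase, stood at -0.51 ± 0.14 (adjusted p = 0.149, block 0.0325), the polymerase subunit gene POLE2 at -0.43 ± 0.13 (0.203, block 0.0462), MCM6 at -0.30 ± 0.12 (0.365) and CCNE2 at -0.65 ± 0.27 (0.382, block 0.00672). Without negative pressure replicate 3 the S phase median was -0.07 (adjusted p = 0.165) and CCNE2 stood at -0.38. The median was -0.25 without negative pressure replicate 1 and -0.08 without both replicate 3 arrays. Fry gave adjusted p = 0.422 for this list and 0.167 for ribosome biogenesis.

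YAP and TAZ targets had a median of -0.17 over 17 members (adjusted p = 0.00446; adjusted p = 0.566 with an estimated correlation), and none passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05 in limma and 4 that fell with the replicate block. CCN1, a matricellular protein, stood at -0.83 ± 0.30 (SE; adjusted p = 0.30, block 0.00822), FJX1 at -0.56 ± 0.14 (0.134, block 0.0198), ANKRD1 at -0.51 ± 0.19 (0.318) and TGFB2 at -0.44 ± 0.17 (0.349, block 0.0399). Without negative pressure replicate 3, CCN1 stood at -0.44 and TGFB2 at -0.28. The list median was -0.31 with the mean of all probe sets, -0.47 with the probe set of largest variance, and -0.26 both with array weights and without both replicate 3 arrays. The YAP and TAZ call was lost without ambient pressure replicate 1 (0.0601), without negative pressure replicate 3 (0.0824) and in fry (0.450). All 9 metallothionein and zinc genes lay below 0, with a median of -0.15 (adjusted p = 0.0190; adjusted p = 0.238 with an estimated correlation). Their changes were small: MT1G stood at -0.21, MT2A at -0.21, MT1X at -0.19 and MT1H at -0.17. These members were all read on probe sets that the array's own naming marks as liable to cross-hybridise. Their shared sign may therefore be in part 1 signal read several times, for which the preset correlation of camera allows little. None of the 9 passed over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05 in limma. This call was lost without ambient pressure replicate 1 (0.0548), without negative pressure replicate 3 (0.0753) and with array weights (0.0600). Without ambient pressure replicate 3, MT1G stood at -0.09, MT1H at -0.10 and MT2A at -0.13. MT1H stood at -0.11 without negative pressure replicate 2. MT1G turned to 0.05 with the probe set of largest variance, a dim one (mean 2.81, against 10.19 for the main one).

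**Figure D3:**
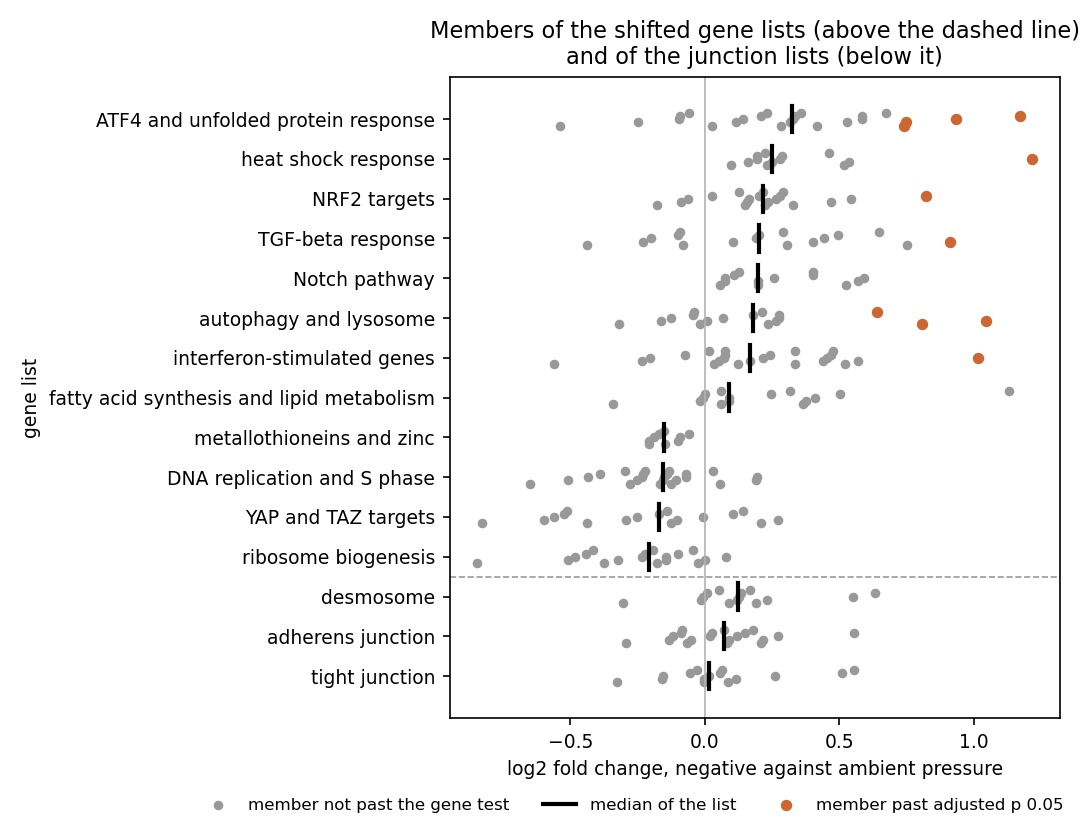
Log2 fold change of each measured member (horizontal axis, negative against ambient pressure) in the 12 lists past the camera threshold, above the dashed line, and in the 3 cell junction lists, below it. Black bars are list medians, from 0.32 for the ATF4 and unfolded protein response to -0.21 for ribosome biogenesis, and coloured points are members past adjusted p 0.05.

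Adherens junction genes were addressed because the study concerned the disassembly of these junctions and p120-catenin. The arrays measure RNA and not the junctions or their proteins, so the values below neither show nor exclude disassembly. None of 19 measured members passed over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05 in limma, and the list median was 0.07 (camera adjusted p = 0.559). With the replicate block 1 rose, NECTIN4 (0.55, adjusted p = 0.351, block 0.0379), singled out after its value was seen. The median was -0.00758 without ambient pressure replicate 3. CDH1, the gene of E-cadherin, was at 10.48 ± 0.12 at ambient and 10.63 ± 0.10 under negative pressure (SD, n = 3 each; log2 fold change 0.15 ± 0.12, SE; limma adjusted p = 0.755). P-cadherin CDH3 stood at 0.12 ± 0.13 (adjusted p = 0.844), alpha-catenin CTNNA1 at 0.08 ± 0.11 (0.874) and the kinase gene SRC at 0.17 ± 0.13 (0.730). When 1 array was left out, CDH3 ran from 0.05 to 0.21, CTNNA1 from 0.05 to 0.10 and SRC from 0.08 to 0.24. Beta-catenin CTNNB1 stood at -0.12 ± 0.37 (adjusted p = 0.955), with 8.52 and 8.58 on the replicate 3 arrays of the groups against 9.47 to 9.89 on the other 4 arrays. Its sign turned with another choice of probe sets (0.02 with their mean, 0.16 with the largest variance) and without ambient pressure replicates 1 (0.15) or 2 (0.04) or negative pressure replicate 3 (0.21). CTNND1, the gene of p120-catenin, had no probe set that named it alone. The 4 probe sets assigned jointly to it and the readthrough locus TMX2-CTNND1 had log2 fold changes of 0.10, 0.31, 0.46 and 0.47, with adjusted p of 0.986, 0.891, 0.271 and 0.439 among probe sets without 1 gene of their own, and cannot be assigned to either.

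Other junction and adhesion lists did not pass. The desmosome list had a median of 0.12 over 14 members (adjusted p = 0.106; fry adjusted p = 0.0374). None of the 14 passed over all genes, 2 had an unadjusted p under 0.05 in limma, and DSG3 (0.63 ± 0.17, SE; adjusted p = 0.153, block 0.0146) and PKP1 (0.55 ± 0.16, 0.184, block 0.0210), singled out after their values were seen, passed adjusted over the list alone. The tight junction list (median 0.02, 15 members, adjusted p = 0.508), the hemidesmosome and cell-matrix adhesion list (-0.00193, 15 members, 0.997) and the actin cytoskeleton (-0.12, 17 members, 0.116) had no member past the threshold over all genes or adjusted over the list alone. The actin median was 0.02 without negative pressure replicate 3. When 1 array was left out, the tight junction median ran from 0.03 to 0.10. Members of these lists, in the order given, at an unadjusted p under 0.05 in limma numbered 2, 1 and 2. With the replicate block 1 member of these lists rose, the tight junction gene CLDN4 (0.55, adjusted p = 0.139, block 0.0156), singled out after its value was seen.

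In the epithelial-mesenchymal transition list (camera adjusted p = 0.282; 0.0427 with the probe set of largest variance; fry adjusted p = 0.0319), the transcription factor gene TWIST1 rose by 0.88 ± 0.12 (SE; adjusted p = 0.0211) and S100A4, a calcium-binding protein, by 0.83 ± 0.12 (adjusted p = 0.0211). The other 13 members did not pass, the same 2 rose adjusted over the list alone, and the median (-0.03) lay on the other side of 0 from the mean (0.12). Hypoxia response genes did not pass as a group (median 0.03 over 31 members, adjusted p = 0.379; 0.0485 with the probe set of largest variance), and their 3 changed members went both ways: DDIT4 and the collagen hydroxylase gene P4HA2 (0.70 ± 0.11, adjusted p = 0.0280) rose and PDK1 fell. Adjusted over the list alone, and also over all genes with the replicate block, 5 rose and 1 fell, and P4HA2 stood at 0.33 (adjusted p = 0.180) with the mean of its probe sets. The cytokine genes IL1A (-0.94 ± 0.15, adjusted p = 0.0299) and IL1B (-0.64 ± 0.12, adjusted p = 0.0413) fell among 23 inflammatory genes, of which 21 did not pass (median -0.05, adjusted p = 0.0939). The inflammatory list passed with the probe set of largest variance (adjusted p = 0.0351) and, with a median of -0.13, without ambient pressure replicate 2 (0.0232). Adjusted over the list alone, and also over all genes with the replicate block, 6 of these fell and 3 rose, and IL1A stood at -0.29 (adjusted p = 0.244) with the mean of its probe sets. The other probe set of IL1A, dim at a mean of 2.67 against 10.05, stood at 0.36. Of 21 immediate early genes, JUNB rose (0.67 ± 0.12, adjusted p = 0.0396), FOSL1 fell and 19 did not pass. The list median was -0.11 (camera adjusted p = 0.244) and ran from -0.15 to -0.04 when 1 array was left out. Over that list alone JUNB rose and FOSL1 and JUN (-0.71, adjusted p over all genes 0.138, block 0.0110) fell, JUN being singled out after its value was seen. Over all genes, 3 rose and 3 fell with the replicate block. The call of JUNB was lost with quantile normalization (0.66, adjusted p = 0.0572) and cyclic loess (0.65, 0.0574). Those of FOSL1 (-1.05, 0.0637) and IL1B (-0.65, 0.0505) were lost with median centring. The log2 fold changes were close to those of the main fit. With the probe set of largest variance the calls of JUNB (0.67, adjusted p = 0.0669) and P4HA2 (0.70, 0.0501) were lost at unchanged folds, and that of IL1B (-0.62, 0.139). The call of IL1B was also lost with both replicate 3 arrays left out (-0.63, 0.0520).

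AQP3 was the 1 of 16 aquaporin, ion channel and mechanosensor genes that rose, over all genes and adjusted over the list alone (median 0.10, adjusted p = 0.101; fry adjusted p = 0.0282), and 2 rose with the replicate block. The lists of keratinocyte state did not pass, with medians of 0.01 for terminal differentiation (22 members, adjusted p = 0.688), 0.10 for basal keratinocyte genes (10 members, 0.175) and 0.03 for activated and simple keratins (7 members, 0.605). Matrix proteases and wound migration (-0.07, 18 members, 0.456), WNT and beta-catenin targets (-0.05, 16 members, 0.162), p53 targets (0.08, 15 members, 0.606) and mitosis and G2/M (-0.03, 24 members, 0.270) did not pass either. The mitosis list passed without ambient pressure replicate 3 (median -0.10, adjusted p = 0.0116) and without both replicate 3 arrays (-0.05, 0.0386). Cholesterol synthesis and uptake (0.02, 16 members, 0.997), nuclear-encoded oxidative phosphorylation (0.01, 23 members, 0.997) and cytosolic ribosomal proteins (0.01, 19 members, 0.997) did not pass. No member of these 10 lists passed over all genes, and between 0 (ribosomal proteins) and 4 (terminal differentiation, matrix proteases, WNT targets and cholesterol synthesis) had an unadjusted p under 0.05 in limma. Adjusted over the list alone, the nerve growth factor receptor gene NGFR rose (0.94, adjusted p over all genes 0.135, block 0.00109), and MMP10 (-0.76, 0.101, block 0.0171), the WNT inhibitor gene DKK1 (-0.83, 0.0750, block 0.0124), AEN (-0.57, 0.0859, block 0.0226), ZMAT3 (-0.51, 0.155, block 0.0349) and HMGCS1 (-0.88, 0.0912, block 0.00188) fell, all singled out after their values were seen. With the replicate block, members past the threshold over all genes were 1 lower for terminal differentiation and for cholesterol synthesis, 1 higher for basal keratinocyte genes and 2 higher for activated and simple keratins. They were 1 higher and 2 lower for matrix proteases, and 2 lower each for WNT targets, p53 targets and mitosis. Camera's direction was down for the lists of terminal differentiation, p53 targets, cholesterol synthesis, oxidative phosphorylation and ribosomal proteins, opposite to the sign of their medians.

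Markers of other cell types did not pass camera as groups with 1 probe set per gene chosen by its mean. Medians were 0.02 for fibroblast markers (10 members, adjusted p = 0.754), 0.04 for melanocyte markers (8 members, 0.413), 0.03 for leukocyte markers (10 members, 0.696) and -0.01 for endothelial markers (9 members, 0.282). Melanocyte markers passed in fry (adjusted p = 0.0161), with 7 of 8 above 0, and fibroblast markers passed camera with the probe set of largest variance (median 0.21, adjusted p = 0.0427). CDH5, the gene of VE-cadherin, was the 1 endothelial marker that fell, over all genes and adjusted over the list alone, from 4.81 ± 0.09 to 4.01 ± 0.21 (SD, n = 3 each; limma adjusted p = 0.0325). That call was lost with both replicate 3 arrays left out (-0.73, adjusted p = 0.0542) and, at an unchanged -0.80 on its 1 probe set, with the probe set of largest variance (0.0530). No member of the other 3 lists passed by either adjustment, and none had an unadjusted p under 0.05 in limma.

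In all, 12 of 37 lists passed camera with its preset correlation of 0.01, 8 up and 4 down, and the same 12 passed with the replicate block. With an estimated correlation none passed, 7 had an unadjusted p under 0.05, and fry called 12 lists in 1 direction and 19 in either direction. The 12 that fry called in 1 direction were not the 12 of camera. Ribosome biogenesis, S phase, YAP and TAZ targets and autophagy were lost. The desmosome, epithelial-mesenchymal transition, aquaporin and melanocyte lists were called instead.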

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

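The tests on the replicate 3 arrays were chosen after the result was seen.

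Probe sets outside the comparison of genes carried signal too. Of 13522 probe sets with no gene name here or with several, 12 passed adjusted p 0.05 in limma, 5 higher and 7 lower under negative pressure. The largest rise among them, 2.27 ± 0.13 on the log2 scale (SE; adjusted p = 0.000108), was that of 1 probe set, from 7.00 ± 0.16 to 9.27 ± 0.14 (SD, n = 3 each). It exceeded the rise of every gene with a probe set of its own that the report names, AQP3 (1.93) included. The largest fall among the 12 was -1.90 (adjusted p = 0.0181), on a probe set whose several assigned genes include DLEU2. Both probe sets are assigned to several genes, so they name none.

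Chance can be weighed only coarsely, since 6 arrays split into 3 and 3 in 10 ways and no share under 0.05 can be reached. For the 182 genes, 1 of the 10 splits, the real one, gave as many, and the highest of the others gave 0. For the 12 lists, 1 of the 10 splits gave as many, and the highest of the others gave 5. The 3 other splits that part all same-numbered pairs called 0 genes and at most 3 lists, and those that keep a pair together called 0 genes and at most 5 lists. Every split but the real one mixes both pressures within its groups. A difference between pressures would thus widen the spread in those splits, and their 0 genes are no measure of chance. Most of them still called lists without any gene.

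The replicate 3 arrays of both groups stood apart from the other 4 on the first principal component. More degraded RNA in replicate 3 is argued against by the ACTB controls, whose 3' minus 5' difference on the replicate 3 arrays was smaller than on the others of their group (mean difference -0.41 on the log2 scale). A technical difference in the hybridization of these arrays stays open and is in line with the bacterial and phage controls added to every array, of which 18 of 18 probe sets were lowest on replicate 3 in each group (median differences -0.42 and -0.27 on the log2 scale). These probe sets stand for a few added transcripts and are not independent. A biological difference between the cultures numbered 3 and the others was not tested.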

How the results depend on the processing

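Leaving out both replicate 3 arrays and replicate 3 as a batch term were chosen after seeing the data; the other alternatives were fixed beforehand. The 182 genes changed under negative pressure became 976 with the replicate block, 1145 with array weights, 1213 with replicate 3 as a batch term and 372 without both replicate 3 arrays, the first 3 including all 182 and the last 167 of them. Other thresholds gave 53 (2-fold as well) and 352 (adjusted p under 0.10), and leaving out 1 array gave 7 to 145, with fewer arrays in the fit. Other normalizations gave 221 genes (quantile repeated; 132 higher, 89 lower; 172 of the 182), 146 (median centring; 97 and 49; 146 of them) and 240 (cyclic loess; 135 and 105; 178 of them), against 120 higher and 62 lower, and the median of all genes stayed within 0.1 of 0. The 12 lists became 0 with an estimated correlation (7 at an unadjusted p under 0.05), 19 with fry in either direction and 9 to 13 when 1 array was left out. For the fixed lists reported and their members, the replicate block changed no other call than those given in the report as blocked counts or values. Of the 41 named genes that passed, 40 kept their sign in each alternative; 29 stayed past the threshold with the mean of all probe sets and 5 to 35 when 1 array was left out. AQP3, LOC105379499 and TMT1A passed in all 17 alternatives. PIGL turned to -0.0191 with the mean of all probe sets, since its probe sets moved in opposite directions (1.23 and -0.87). CTNNB1 turned to 0.0162 with the mean of all probe sets and 0.16 with the largest variance, and ran from -0.54 to 0.21 when 1 array was left out; MT1G turned to 0.0460 with the largest variance. Medians of further uncalled lists changed sign when 1 array was left out without a turn in camera, such as those of adherens junction (-0.00758 to 0.13), actin cytoskeleton (-0.15 to 0.02) and epithelial-mesenchymal transition (-0.05 to 0.08). For these, CTNNB1 and MT1G the cause was not tested.

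The reported lists whose direction in the test turned were all uncalled, with medians near 0; the cause was not tested. Medians were as follows under the settings that turned them, and ranges are those over all fits with 1 array left out, whether or not these turned the list. Cholesterol synthesis: 0.0227 with the replicate block, the batch term and fry, 0.0391 with array weights, 0.0267 without both replicate 3 arrays, and 0.00511 to 0.0407 when 1 array was left out. Ribosomal proteins: 0.0120 with quantile normalization, 0.0160 with the mean of all probe sets, 0.0304 with the largest variance, 0.0117 with trend and robust variance and with fry, 0.0178 with array weights, 0.0210 without both replicate 3 arrays, and -0.00387 to 0.0205 when 1 array was left out. Oxidative phosphorylation: 0.0111 with trend and robust variance and with fry, 0.0222 with array weights, 0.0238 without both replicate 3 arrays, and -0.00123 to 0.0357 when 1 array was left out. Leukocyte markers: -0.0257 with array weights, 0.00146 without both replicate 3 arrays, and -0.0307 to 0.0868 when 1 array was left out. Hemidesmosome and cell-matrix adhesion: -0.00193 with fry and -0.0408 to 0.0529 when 1 array was left out. Matrix proteases ran from -0.0850 to 0.0196 and terminal differentiation from -0.0341 to 0.0515 when 1 array was left out. With 3 arrays per group, changes well under 2-fold are often missed.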

Other observations

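The lists of FOXO targets, aryl hydrocarbon receptor targets, histone genes, chaperone families and cold-inducible genes (CIRBP, RBM3) were chosen after values of some members were seen. SERPINH1 was singled out after its value was seen, and the tests on the replicate 3 arrays and on HSF1 targets outside the chaperone families were chosen after the result was seen.

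Several genes known as targets of FOXO transcription factors rose under negative pressure. Of 17 measured members, 5 rose: DDIT4 (1.24), the glucocorticoid-induced leucine zipper gene TSC22D3 (1.03 ± 0.11, SE; limma adjusted p = 0.0116), the transcriptional repressor gene BCL6 (0.89 ± 0.17, adjusted p = 0.0483), GABARAPL1 (0.81) and the antiproliferative gene BTG1 (0.64 ± 0.12, adjusted p = 0.0473). None fell, 15 of 17 lay above 0, and the median was 0.43. As the list was put together after some members had been seen to be high, its shift as a group is not tested by these data. TXNIP stood at 0.85 (adjusted p = 0.115, with the replicate block 0.0232) and CCNG2 at 0.64 (0.0947, block 0.0258). Lists fixed beforehand also hold DDIT4, GABARAPL1, PDK4, SESN1 and KLF6.

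The xenobiotic-metabolising genes CYP1A1 (0.63 ± 0.12, adjusted p = 0.0483) and CYP1B1 (0.73 ± 0.12, adjusted p = 0.0296) rose, while the other 5 of 7 aryl hydrocarbon receptor targets did not pass (median 0.07). AHRR stood at 0.05 and TIPARP at -0.00193, and NQO1 is also in the list of NRF2 targets. Of 42 replication-dependent histone genes, 3 rose: H2AC6 (1.25), H2BC5 (0.97 ± 0.14, adjusted p = 0.0211) and H2BC21 (0.76 ± 0.14, adjusted p = 0.0455). H2AC25 stood at 0.53 (adjusted p = 0.0823, block 0.0184). None of the 42 fell and the median was 0.00355.

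Of 30 genes of the DNAJA, DNAJB, HSPA, HSPB and HSPH families outside the heat shock list, 5 rose, none fell and the others did not pass, with a median of 0.11, and as these families were chosen after some members had been seen to be high, their shift as a group is not tested by these data. HSPB8 (1.10), HSPA4L (1.07), DNAJA4 (1.05), DNAJB4 (0.95), DNAJB2 (0.74) and the collagen chaperone gene SERPINH1 (0.96) rose, HSPA14 (-0.50, block 0.0355), DNAJB6 (0.68, block 0.0185) and HSPA1L (0.57, block 0.0220) passed with the replicate block alone, and of the 2 cold-inducible RNA-binding protein genes CIRBP fell and RBM3 stood at -1.24 ± 0.32 (SE; adjusted p = 0.139, block 0.000358). Between the same-numbered arrays of replicates 1 and 2, the median change of 6 chaperone genes exceeded that of CIRBP and RBM3. The 6 were HSPB1, HSPB8, DNAJA4, SERPINH1, HSPA4L and DNAJB4. The excess was at least 2.13 on the log2 scale, so the pattern was not confined to the replicate 3 arrays. These genes were picked on values of all 6 arrays, so this outcome was nearly fixed beforehand and does not test the source. A warmer or otherwise HSF1-activating culture under negative pressure may account for the pattern. The 17 HSF1 targets not looked at before had a median of 0.18, within the SD of the members (0.27), with 13 above 0. Camera gave an unadjusted p of 0.0314, and 0.254 with an estimated correlation. No adjusted p is given, as it would rest in part on lists chosen after values were seen. None of the 17 passed over all genes in limma, where 6 had an unadjusted p under 0.05. Without the 6 that the families above also hold, the median of 11 was 0.19 with 9 above 0. Camera gave these 11 an unadjusted p of 0.00850, and 0.0836 with an estimated correlation. HSPA6 stood at 0.05 (limma adjusted p = 0.948). Probe sets shared by HSPA1A and HSPA1B stood at 0.37, 0.71 (also shared with HSPA1L) and 0.55. The latter had limma adjusted p of 0.674, 0.0509 and 0.939 among probe sets without 1 gene of their own. An effect of pressure itself on chaperone genes was not tested apart from that of such a culture and stays open. The fall of CIRBP rests on some of its probe sets (-0.37 with the mean of all).

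AQP3 had the largest rise of the genes that the report names, on its brightest probe set (1.93), while its other 2 probe sets stood at 0.59 and 0.57 and the mean of all at 1.03, below RSRP1 (1.11). Between the same-numbered arrays of replicates 1 and 2, AQP3 rose by at least 1.59 on the log2 scale. Its rise was thus not confined to the replicate 3 arrays. AQP3 was picked for a large rise without overlap of the groups. That outcome was therefore nearly fixed beforehand and does not test the source. A hyperosmotic medium, for example from evaporation, might raise AQP3, and a median of 0 or lower over osmotic response genes was to speak against it. The median of 10 was -0.0107, which met that outcome. With 5 above 0 and an SD of 0.50 it lies within their spread, and so near 0 it decides little. The prediction itself had set no bar on the spread. SLC5A3 stood at 0.30 (adjusted p = 0.550), SLC6A6 at -0.51 (0.395), SLC6A12 at -0.03 (0.959) and SGK1 at -0.61 (block 0.0107). AKR1B1 had no probe set of its own, and HSPA4L (1.07), which rose, had been seen before. A response of AQP3 to negative pressure stays open, as untested.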
